A study of Rattus norvegicus with 40 samples.

How the data were processed

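Gene expression was measured in INS-1 832/13, a rat insulinoma cell line used as a model of the insulin-secreting beta cell. Cells were left untreated (control) or were exposed to inorganic sodium arsenite (iAs) or to methylarsine oxide (MAs), a trivalent methylated arsenical. Libraries of 3 kinds were made, per the labels: ChRO-seq, which captures RNA still attached to engaged RNA polymerase and so reports transcription, RNA-seq of total RNA, and small RNA-seq for microRNAs. The labels name the ChRO protocol, the NEBNext Ultra II kit for RNA-seq and the TriLink CleanTag kit for small RNA-seq. The series held 40 samples, with 12 ChRO, 14 RNA and 14 small RNA libraries. Each label carries a batch letter, K or R, and a library is named here by its treatment, its batch letter and its number in the deposited tables, such as iAs K3. The labels used here give no dose and no exposure time, and they do not say that libraries came from separate cultures. All p-values below therefore measure only the spread between these libraries, part of which may be technical.

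All values came from tables of the whole series that the authors deposited, in which each feature has a normalized count, a signal value obtained by the authors by dividing read counts by DESeq size factors, per the names of the deposited tables. The submitters' processing notes name STAR, Salmon and DESeq2 without versions and the genome build rn6; which tool made which table is not given in the sources used here. There were 21305 genes with ChRO values, 32754 genes with RNA values, 1280 small RNA features in the iAs experiment and 1388 in the MAs experiment. No column of per-sample values was left unused. Gene symbols were those paired with gene identifiers in the tables. Of the RNA genes 19207, and of the ChRO genes 16529, were also found in a gene table of the GRCr8 assembly, which was used for names, chromosomes and which genes lie between others, with none of its coordinates printed. The ChRO table held 16 genes of chromosome X where the RNA table held 701, and it lacked Ins1 and Mt1.

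Depth was read back from the values. Normalized ChRO and small RNA values came out as whole multiples of the worth of 1 read, within 0.05 reads, for 100% of the values in every library. These steps gave 998734 (iAs K3) to 6958908 (control K3) reads per ChRO library, and 7069979 (control R1) to 16822231 (iAs R2) reads per small RNA library of the iAs table. The MAs small RNA libraries had 12417108 (MAs K2) to 22201358 (MAs K3) reads. Only 7.36% to 24.59% of the RNA values came out whole, so the depth of the RNA libraries is unknown. The 10 highest features held 8.5% to 10.7% of an RNA library, 2.0% to 2.9% of a ChRO library and 49.2% to 53.8% of a small RNA library. Small RNA counts under 10 were listed as 0. The 2 controls of the MAs small RNA table were the 2 batch K controls of the iAs table, with equal recovered reads for 1280 of the 1280 shared features. Pairs of ChRO and of small RNA libraries of 1 group and batch differed by more than sampling noise, with a lowest chi-square per degree of freedom of 2.04, for ChRO control K2 and control K3. RNA values are not reads and were not tested this way, and 0% of the values above 0 were equal in 27 pairs of RNA libraries of 1 group.

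Groups were compared with limma 3.58.1 (trend and empirical Bayes) in R 4.3.3 on log2(normalized count + 1), two-sided, over features with a mean normalized count of at least 10. A fold change on this scale understates the change of low genes. Batch was an additive term, and the RNA and ChRO fits used all 3 treatment groups, which then shared 1 estimate of the spread. All libraries of the MAs small RNA table were of batch K, so that fit had no batch term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and "rose" and "fell" refer to such calls. Adjusted p-values without a named tool come from limma. Values before ± are means of normalized counts and those after it are SDs, unless the SE of a log2 change is named. RNA and ChRO changes were compared per gene in 1 limma fit over both tables, as the RNA change minus the ChRO change, with 1 level per assay and batch. The correlation of the iAs and MAs changes was set beside 100 simulations of unchanged groups that shared the controls.

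Gene lists were written from textbook knowledge before the data were examined, as were the tests, the batch term, the alternatives and the rule for named genes. They covered NRF2 targets, the heat shock response, metallothioneins and metal transport, the ATF4 stress response, ER chaperones, p53 targets, immediate early genes, the interferon response, beta cell transcription factors, insulin granule proteins, glucose sensing and exocytosis, mitotic genes, DNA replication genes, cholesterol synthesis, glycolysis and hypoxia targets, respiratory chain subunits, cytosolic ribosomal proteins and literature targets of miR-29. Markers of other islet endocrine cells, acinar cells, duct cells and fibroblasts were added for cells other than beta cells. The microRNA lists were the miR-29 family, the miR-200 family, the miR-183 cluster, beta cell enriched microRNAs, stress and p53 responsive microRNAs, the let-7 family, the miR-17-92 cluster and microRNAs of other cell types. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The camera test asks whether the members of a list moved more than the other genes. Calls within a list were also counted after adjusting over the list alone.

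Named genes followed a rule. For RNA and ChRO against control they were the 6 largest rises and 6 largest falls among called genes with a mean of at least 50 and every treated library on the same side of the mean of the controls of its batch, without unnamed loci. For MAs against iAs and for RNA minus ChRO, 5 in each direction were taken, and the rule on every library did not apply to RNA minus ChRO. Up to 4 called members per gene list with the largest changes were added (where none was called, the 2 members with the highest mean), with Ins1 and Ins2 in any case. For small RNA the rule took 8 in each direction, the miR-29 family, miR-375-3p and up to 3 per microRNA list, or the 5 smallest p-values where no feature was called. Some genes that the rule takes are not reported here. Genes whose reads can be shared with near-identical copies, such as Ins1 and Ins2, Mt1, Gsta1 and the ribosomal protein genes, carry that uncertainty.

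The tests were checked on simulated data with 200 changed genes and known folds. In RNA limma recovered 48% of genes changed 1.5-fold and 74% of those changed 2-fold for iAs, and 52% and 80% for MAs. For ChRO it recovered 26% and 59% for iAs and 19% and 70% for MAs. For small RNA it recovered 66% and 86% for iAs, and 4% and 35% for MAs. For RNA minus ChRO with iAs it recovered 7.3% and 46.8%. False calls numbered at most 9. Of 22 sets camera called only the planted one, but correlated genes were not tried.

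Alternatives were other pseudocounts (0.5 and 8), no filter or a mean of at least 100, rescaling to equal totals, quantile normalization, no batch term, each batch alone, fits of the compared groups only, no trend, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads of ChRO and small RNA. A block on the number in the column name was added after the data were seen. Splits of the samples into other groups of the same sizes were counted, with at most 100 splits per comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.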

Results

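The comparisons used 14 RNA libraries, 12 ChRO libraries and 14 small RNA libraries of INS-1 832/13 cells. RNA-seq covered 4 control, 4 iAs and 6 MAs libraries. ChRO-seq covered 4 libraries of each treatment, and both assays held libraries of batches K and R in every group. Small RNA-seq covered 5 control and 5 iAs libraries over both batches, and 4 MAs libraries of batch K that were compared with the 2 controls of that batch. Recovered depth was 998734 to 6958908 reads per ChRO library and 7069979 to 22201358 reads per small RNA library, whereas the depth of the RNA libraries is unknown. Control RNA libraries held 745300 ± 145300 (SD, n = 4) normalized counts of Ins1 and 7625 ± 3807 (SD, n = 4) of Ins2, the 2 rat insulin genes, whose reads can be confused with each other. The first principal component held 57.8% of the variance of the small RNA libraries with iAs and separated batch K from batch R.

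The first comparison asked which transcripts differed between iAs-treated and control cells. Hmox1, which encodes the heme-degrading and stress-inducible enzyme heme oxygenase, rose 10.4-fold, from 1369 ± 216 (SD, n = 4) to 14420 ± 3354 (SD, n = 4) normalized counts. Mt1, a metal-binding metallothionein, rose 8.67-fold, from 569 ± 155 to 4916 ± 1235 (SD, n = 4 each), and the chemokine gene Cxcl10 rose 12.8-fold, from 250 ± 19.9 to 3213 ± 480 (SD, n = 4 each). Txnip, whose product binds and inhibits thioredoxin, fell from 22840 ± 3959 to 2447 ± 333 (SD, n = 4 each), a 9.28-fold drop. All 4 iAs libraries lay on the same side of the controls of their batch for each of these genes, and the log2 changes were 3.38 (SE 0.26, adjusted p = 3.23e-06) for Hmox1, 3.12 (SE 0.23) for Mt1, 3.67 (SE 0.32) for Cxcl10 and -3.21 (SE 0.31) for Txnip. Other rises were those of Lexm (log2 5.15, SE 0.53), Cd6 (3.11, SE 0.29) and Gsta1, a glutathione transferase (2.73, SE 0.57). Other falls were those of Mmp17, a matrix metalloproteinase (-3.35, SE 0.41), Cpne9 (-3.53, SE 0.45), Cilp2 (-3.28, SE 0.27) and Prok2, a secreted prokineticin (-3.27, SE 0.53). In all, limma called 4125 of 14487 genes, of which 2033 rose and 2092 fell, and 375 rises and 439 falls were at least 2-fold. Equal totals gave 2131 rises and 1747 falls and quantile normalization 2245 and 1801.

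**Figure D1:**
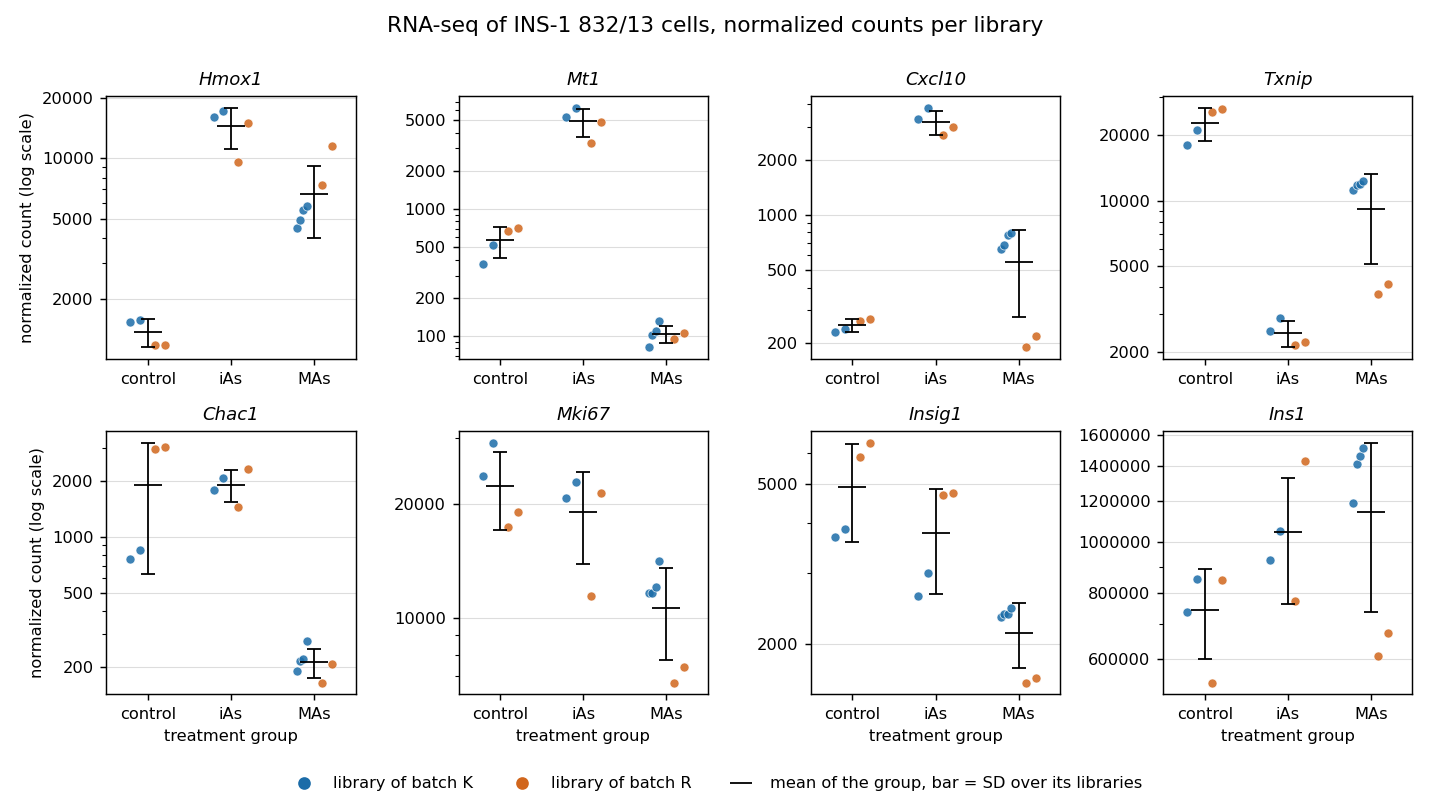
Normalized RNA counts (log axis) of Hmox1, Mt1, Cxcl10, Txnip, Chac1, Mki67, Insig1 and Ins1 in control, iAs and MAs libraries. Each point is 1 library, blue for batch K and orange for batch R, and the bars give the mean and SD; Mt1 lies above the controls in the 4 iAs libraries and below them in the 6 MAs libraries.

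Rises prevailed among NRF2 targets, interferon genes and p53 targets with iAs. Of 21 measured NRF2 targets, the antioxidant genes driven by that transcription factor, 11 rose and 0 fell over all genes, and 11 rose when adjusted over the list alone. They included Nqo1, a quinone reductase (log2 1.35, SE 0.08), Osgin1 (1.35, SE 0.12) and Gclm, a subunit of the enzyme that starts glutathione synthesis (1.23, SE 0.07). The list was called by camera (adjusted p = 3.59e-07) and held its call with an estimated correlation (adjusted p = 0.00337 with an estimated correlation). Of 12 interferon response genes 8 rose, also 8 when adjusted over the list alone, among them the antiviral genes Mx2 (2.08, SE 0.20) and Oas1a (1.63, SE 0.21) and the transcription factor Irf7 (1.03, SE 0.11), with a camera adjusted p = 1.14e-05 and an adjusted p = 0.101 with an estimated correlation. Of 13 p53 targets 6 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.00799, adjusted p = 0.785 with an estimated correlation). The death receptor gene Fas rose by 1.57 (SE 0.17), the stress cytokine gene Gdf15 by 1.36 (SE 0.18) and the apoptosis gene Bax by 0.68 (SE 0.12). Of 6 metallothionein and metal transport genes 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.607), with Mt3, another metallothionein, at 1.25 (SE 0.17) and the zinc importer Slc39a14 at -0.74 (SE 0.11). Of 20 ATF4 targets, genes of the response to amino acid and ER stress, 4 rose and 0 fell, also 4 adjusted over the list alone (camera adjusted p = 0.315), and Atf5 (0.63, SE 0.13) and Sesn2 (0.35, SE 0.08) were among them. The ATF4 list went opposite ways in the batches: 15 rose and 0 fell in batch K alone (camera adjusted p = 1.16e-05, median 0.567), whereas in batch R alone 0 passed limma over all genes and 1 rose and 6 fell over the list alone (camera adjusted p = 0.0298, median -0.362). ER chaperone genes had 1 rise among 19, also 1 over the list alone, that of the ubiquitin ligase gene Syvn1 (0.33, SE 0.08). Heat shock genes had 1 rise among 16 and 0 by limma adjusted over the list alone, and the adjusted camera p was 0.725 for both lists.

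Falls prevailed in lists of ribosomal, glycolytic and cell-division genes with iAs. Of 18 cytosolic ribosomal protein genes 13 fell, also 13 adjusted over the list alone, with Rpl13 at -0.64 (SE 0.16), Rpl3 at -0.62 (SE 0.10) and Rpl4 at -0.56 (SE 0.12). The camera adjusted p was 6.03e-05, and reads of such genes can be shared with pseudogenes. Of 15 glycolysis and hypoxia targets 7 fell and 9 fell when adjusted over the list alone (camera adjusted p = 0.00181), including the collagen-modifying enzyme gene P4ha1 (-1.16, SE 0.16) and Pdk1, a brake on pyruvate entry into mitochondria (-0.84, SE 0.18). Of 20 DNA replication genes 7 fell, also 7 over the list alone (camera adjusted p = 0.026), with the helicase subunit gene Mcm7 at -1.18 (SE 0.14) and the polymerase gene Pola1 at -0.68 (SE 0.14). Of 19 mitotic genes 5 fell, also 5 over the list alone (camera adjusted p = 0.0189), with the checkpoint kinase gene Bub1 at -0.65 (SE 0.14) and the topoisomerase gene Top2a at -0.61 (SE 0.14). These 4 lists lost their calls when the correlation was estimated (adjusted p = 0.785 with an estimated correlation). Cholesterol synthesis had 2 falls among 20 genes, also 2 over the list alone (camera adjusted p = 0.0763), with Stard4, a cholesterol carrier, at -0.68 (SE 0.17). Respiratory chain genes had 1 rise and 1 fall among 17, and 0 of either by limma over the list alone (camera adjusted p = 0.133).

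Beta cell lists were mixed with iAs. Of 19 insulin granule protein genes 6 rose, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.785 with an estimated correlation). They included Vgf (log2 0.81, SE 0.20) and Scg2 (0.68, SE 0.15), which encode granin peptide precursors, Ptprn, a granule membrane protein gene (0.80, SE 0.08), and Pam, a peptide-amidating enzyme gene (0.78, SE 0.08). Of 23 glucose sensing and exocytosis genes 1 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.101), with the calcium channel gene Cacna1a at -1.16 (SE 0.15). Of 18 beta cell transcription factors 2 rose and 3 fell, also over the list alone (camera adjusted p = 0.821). Nkx6-1 rose by 0.92 (SE 0.08) and Myt1 fell by 0.73 (SE 0.07), while the list had a median of -0.013 and a mean of 0.027, and its median turned to 0.013 with equal totals and 0.002 with quantile normalization. Ins1 had a log2 change of 0.47 (SE 0.28, adjusted p = 0.214) and Ins2 one of 0.27 (SE 0.34, adjusted p = 0.586), neither past the test.

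Immediate early genes went both ways with iAs, with 4 rises and 3 falls among 20, also over the list alone (camera adjusted p = 0.996, median 0.005, mean -0.06). Maff, which encodes a small partner of NRF2, rose by 1.71 (SE 0.16), and the growth regulators Myc (-1.34, SE 0.10), Jun (-1.18, SE 0.12) and Klf2 (-2.17, SE 0.51) fell. Literature targets of miR-29 had 4 falls and 0 rises among 18, also 4 over the list alone (camera adjusted p = 0.0763), and the collagen gene Col5a3 was at -1.17 (SE 0.27). Markers of other cell types moved too. Of 3 acinar genes 1 rose and 2 rose over the list alone. Of 4 duct genes 1 rose and 1 fell, also over the list alone, with the transcription factor gene Sox9 at -2.88 (SE 0.34). Of 2 measured genes of other islet endocrine cells 1 rose, and 2 over the list alone. Of 6 fibroblast genes 1 rose, the surface antigen gene Thy1 (0.62, SE 0.10), and 1 fell, against 2 and 1 over the list alone. The fibroblast list had a median of -0.083 and a mean of -0.176 with an upward camera test (adjusted p = 0.725).

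Changes with iAs in the RNA of batch K and of batch R correlated across genes with r = 0.668, genes not being independent replicates, and 6 genes differed in their change between batches. Hmox1 had a log2 change of 3.41 in batch K and 3.34 in batch R, Txnip one of -2.86 and -3.57, and Nqo1 one of 1.40 and 1.31. Batch R alone gave 186 genes, a fit without the batch term 2045 genes, and leaving out iAs K3 2620 genes. Among the named genes past the test, 22 of 77 lost their call when some 1 library was left out; the genes named above with values past the test kept theirs, and so did every gene named in the paragraphs on the other RNA comparisons except where stated.

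The second comparison asked which transcripts differed between MAs-treated and control cells. Cell-division genes fell as a group: all 19 measured mitotic genes were lower, with Ccna2, a cyclin, at a log2 change of -1.38 (SE 0.14), Bub1 at -1.23 (SE 0.13), the mitotic kinase gene Plk1 at -1.20 (SE 0.16) and the proliferation marker Mki67 at -1.20 (SE 0.15), from 22310 ± 5225 (SD, n = 4) to 10620 ± 2905 (SD, n = 6) normalized counts. Mt1 went down, from 569 ± 155 (SD, n = 4) to 104 ± 16.7 (SD, n = 6) normalized counts, a 5.29-fold drop (log2 -2.40, SE 0.21, adjusted p = 5.61e-06). Chac1, a glutathione-degrading enzyme gene of the ATF4 response, fell 7.06-fold, from 1916 ± 1284 (SD, n = 4) to 212 ± 37.1 (SD, n = 6). Hmox1 rose 4.66-fold (log2 2.22, SE 0.24). All 6 MAs libraries lay on the same side of the controls of their batch for each of these genes. Among the other rises were Gsta1 (4.34, SE 0.53), Lexm (3.70, SE 0.49), the potassium channel gene Kcnj5 (3.05, SE 0.30), the aldehyde oxidase gene Aox1 (2.73, SE 0.21), the oxytocin receptor gene Oxtr (2.51, SE 0.19) and Cfap43 (2.48, SE 0.41). Among the falls were Inhbe, an activin subunit gene (-4.77, SE 0.45), from 111 ± 31.0 (SD, n = 4) to 4.15 ± 2.16 (SD, n = 6), Prok2 (-3.46, SE 0.49), Cilp2 (-3.05, SE 0.25), Mgarp (-2.91, SE 0.79) and Gas7 (-2.79, SE 0.58). In all, limma called 4738 of 14487 genes, of which 2260 rose and 2478 fell, with 380 rises and 469 falls of at least 2-fold. Equal totals turned the balance to 2685 rises and 1986 falls, and quantile normalization to 2563 and 2282.

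Falls prevailed in lists of cell-division, lipid and metabolic genes with MAs. The mitotic list had 19 falls adjusted over the list alone as well (camera adjusted p = 5.15e-14, adjusted p = 0.228 with an estimated correlation). Of 20 DNA replication genes 17 fell, and 19 over the list alone (camera adjusted p = 2.86e-08, adjusted p = 0.228 with an estimated correlation). The nucleotide-making Rrm2 (-1.20, SE 0.16) and the helicase subunit gene Mcm7 (-0.84, SE 0.13) were among them. Of 20 cholesterol synthesis genes 16 fell, and 17 over the list alone (camera adjusted p = 2.23e-06, adjusted p = 0.333 with an estimated correlation), with the sterol sensor gene Insig1 at -1.16 (SE 0.21) and the late-pathway reductase gene Dhcr7 at -1.01 (SE 0.16). Of 15 glycolysis and hypoxia targets 11 fell, and 13 over the list alone (camera adjusted p = 4.3e-05), with the glycolytic enzyme genes Pfkp at -1.22 (SE 0.13) and Pgk1 at -1.16 (SE 0.30). Of 20 ATF4 targets 1 rose and 10 fell, and 3 rose and 12 fell over the list alone (camera adjusted p = 0.000751). Mthfd2 (-1.56, SE 0.20) and Psat1 (-1.53, SE 0.14), of mitochondrial folate metabolism and serine synthesis, fell, as did the growth inhibitor gene Ddit4 (-1.71, SE 0.24). The glycolysis and ATF4 lists had an adjusted p = 0.417 with an estimated correlation. Of 18 ribosomal protein genes 7 fell, also 7 over the list alone (camera adjusted p = 0.000751, adjusted p = 0.552 with an estimated correlation), with Rpl3 at -0.58 (SE 0.09) and Rpl4 at -0.50 (SE 0.11).

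Rises prevailed among NRF2 targets, interferon and heat shock genes with MAs. Of 21 NRF2 targets 11 rose and 1 fell, also over the list alone (camera adjusted p = 3.43e-06, adjusted p = 0.00887 with an estimated correlation), with Osgin1 at 2.08 (SE 0.11) and Nqo1 at 1.71 (SE 0.07). The fall was that of the cystine importer gene Slc7a11 (-1.44, SE 0.42, adjusted p = 0.0175), a call that was lost without control R1 (-1.07, adjusted p = 0.0616), control R2 (-1.22, 0.0572) or MAs R2 (-1.20, 0.0507). Of 12 interferon response genes 5 rose and 1 fell, also over the list alone (camera adjusted p = 0.0104, adjusted p = 0.313 with an estimated correlation), with Oas1a at 1.11 (SE 0.19), Mx2 at 1.09 (SE 0.19) and Irf9 at 0.49 (SE 0.11). Of 16 heat shock genes 6 rose and 2 fell, and 7 rose and 2 fell over the list alone (camera adjusted p = 0.0727), and 7 rose and 0 fell with quantile normalization, where camera called the list (adjusted p = 0.0226). The chaperone gene Hsph1 rose by 1.40 (SE 0.28) and the HSP90 partner gene Chordc1 by 0.76 (SE 0.16). Of 19 ER chaperones 1 rose and 3 fell, also over the list alone (camera adjusted p = 0.0478, adjusted p = 0.639 with an estimated correlation), with the ER stress gene Herpud1 at -1.01 (SE 0.13). Of 6 metal genes 1 rose and 3 fell, also over the list alone (camera adjusted p = 0.0872), with Slc39a14 at -1.08 (SE 0.10) and Mt3 at 0.69 (SE 0.16). Of 13 p53 targets 2 rose and 1 fell, also over the list alone (camera adjusted p = 0.129), with Gdf15 at 1.55 (SE 0.16).

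Beta cell lists were again mixed with MAs. Of 19 insulin granule genes 6 rose and 1 fell, also over the list alone (camera adjusted p = 0.0104, adjusted p = 0.595 with an estimated correlation). Vgf rose by 0.83 (SE 0.18), Ptprn by 0.78 (SE 0.08) and Pam by 0.74 (SE 0.07), and the granule zinc transporter gene Slc30a8 fell by 0.57 (SE 0.14). Of 18 beta cell transcription factors 2 rose and 6 fell, and 6 rose and 6 fell over the list alone (camera adjusted p = 0.923). Nkx6-1 rose by 0.82 (SE 0.08), the insulin gene activator Mafa rose by 0.70 (SE 0.13) and Neurod1 fell by 0.65 (SE 0.11), and the list had a median of 0.058 with a downward camera test. Of 23 glucose sensing and exocytosis genes 4 rose and 4 fell, also over the list alone (camera adjusted p = 0.923), with the granule transport gene Rab27a at 0.71 (SE 0.10), Cacna1a at -1.05 (SE 0.14) and Cplx1 at -0.54 (SE 0.08). The median of that list was -0.014 with an upward camera test, and it turned to 0.047 with equal totals and 0.086 with quantile normalization. Respiratory chain genes had 1 rise and 1 fall among 17, and 1 rise over the list alone (camera adjusted p = 0.967), with Sdhb at 0.29 (SE 0.07) and a median of -0.027 that turned to 0.034 and 0.046 under the same scalings. Ins1 had a log2 change of 0.47 (SE 0.25, adjusted p = 0.18) and Ins2 one of 0.81 (SE 0.31, adjusted p = 0.0618), neither past the test. Ins2 did pass with equal totals (0.87, adjusted p = 0.0263), with quantile normalization (0.87, 0.025) and without control R2 (0.97, 0.0461), iAs R2 (0.78, 0.0347), MAs R1 (1.03, 0.0203) or MAs R2 (adjusted p = 0.033), and Ins1 with quantile normalization (0.48, 0.0112). Immediate early genes had 2 rises and 8 falls among 20, and 3 and 8 over the list alone (camera adjusted p = 0.0863), with Maff at 1.67 (SE 0.15) and the nuclear receptor gene Nr4a1 at -1.16 (SE 0.13).

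Literature targets of miR-29 had 4 falls among 18 genes with MAs, also 4 over the list alone (camera adjusted p = 0.0242, adjusted p = 0.228 with an estimated correlation), with Col5a3 at -2.27 (SE 0.25) and the phosphatase gene Ppm1d at -0.57 (SE 0.07). Of 3 acinar genes 1 rose and 1 fell, also over the list alone. Of 4 duct genes 2 fell, and 1 rose and 2 fell over the list alone, with Sox9 at -2.06 (SE 0.31). Of 6 fibroblast genes 2 rose and 1 fell, also over the list alone (median -0.162, upward camera test, adjusted p = 0.676), with Thy1 at 1.08 (SE 0.09). Of 2 genes of other islet endocrine cells 0 passed limma over all genes or over the list alone. Gcg, the glucagon gene, was at 0.62 (SE 0.34, adjusted p = 0.182), and it passed without MAs R1 (adjusted p = 0.0199).

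The MAs change in RNA differed between batches for 2006 genes, 686 with a more positive and 1320 with a more negative change in batch R, and the changes of the batches correlated across genes with r = 0.435. The genes given here were chosen after their values by batch were seen. Ins2 had a log2 change of 1.51 in batch K and -0.24 in batch R (adjusted p of the difference = 0.00406), Gcg one of 1.54 and -0.69, and Slc2a2, the glucose transporter gene, one of 0.60 and -0.66. Cxcl10 stood at 1.63 and -0.39. Mki67 was at -1.09 and -1.36, and Mt1 at -2.06 and -2.77, with no difference between batches past the test. ER chaperones had 5 rises and 4 falls in batch K alone and 0 rises and 13 falls in batch R alone. Batch R alone gave 2868 genes and a fit without the batch term 2744 genes.

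**Figure D2:**
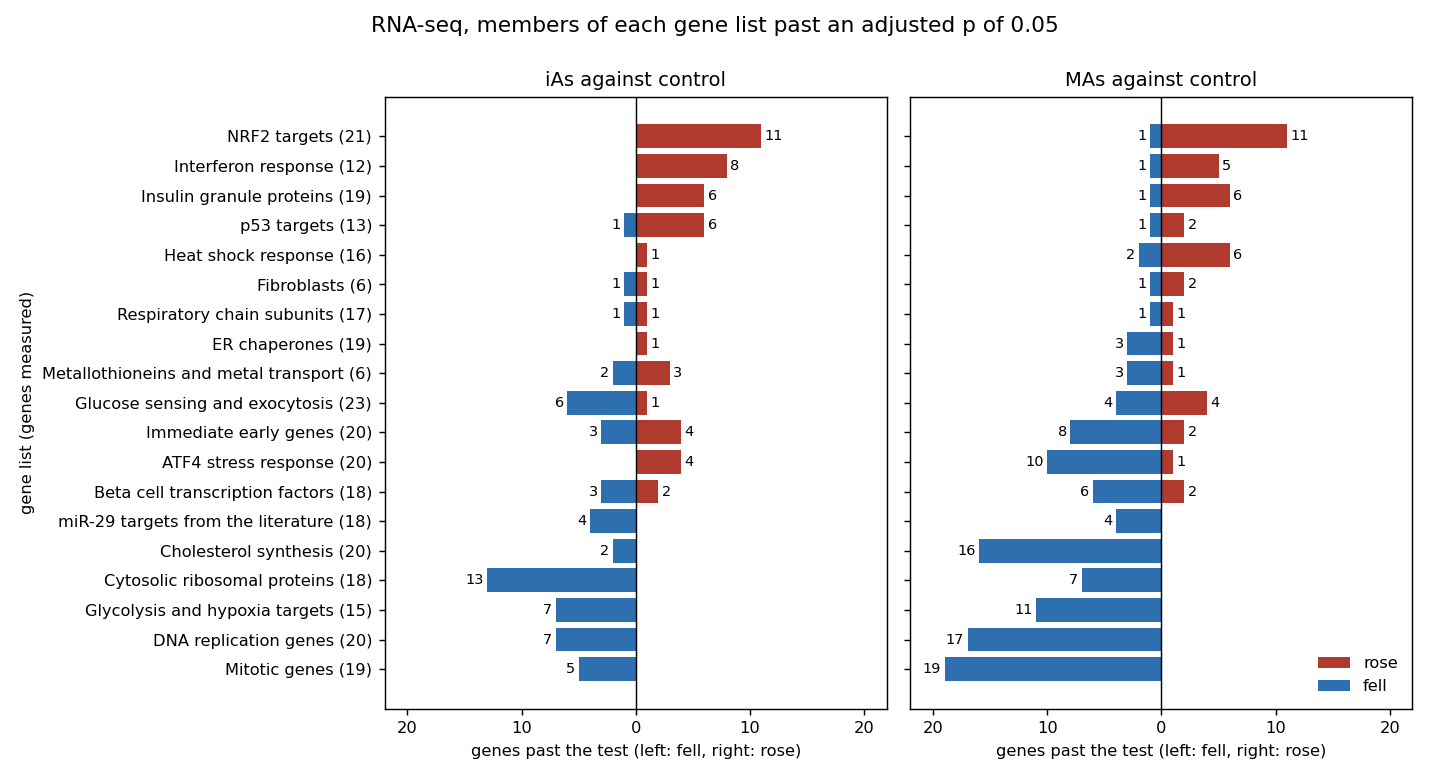
Number of genes per list that rose (right) or fell (left) in RNA with iAs and with MAs against control, limma adjusted p below 0.05 over all genes. The mitotic list has 5 falls with iAs and 19 with MAs, and the ATF4 list has 4 rises with iAs and 10 falls with MAs.

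A direct comparison set MAs against iAs, the methylated against the inorganic arsenical; the labels used here give no doses or times, so it is not known whether these matched. Mt1 was 45.9-fold lower with MAs (log2 -5.52, SE 0.21, adjusted p = 7.22e-09), at 104 ± 16.7 (SD, n = 6) against 4916 ± 1235 (SD, n = 4) normalized counts. Inhbe (-5.62, SE 0.45), the lymphotoxin gene Ltb (-3.31, SE 0.39), Chac1 (-3.09, SE 0.34) and Cxcl10 (-2.88, SE 0.30) were lower with MAs in all 6 libraries. Adam19 (2.23, SE 0.25), Cpne9 (2.14, SE 0.41), Cpne5 (2.13, SE 0.24), the endothelin gene Edn3 (2.00, SE 0.11) and Acot12 (1.95, SE 0.15) were higher. In all, 3255 of 14487 genes differed, 1480 higher and 1775 lower with MAs, and 248 and 280 of these by at least 2-fold. Batch R alone gave 1285 genes, batch K alone 5033 genes and a fit without the batch term 1586 genes.

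Cell-division and ATF4 lists were lower with MAs than with iAs. All 19 mitotic genes were lower, also over the list alone (camera adjusted p = 6.13e-13, adjusted p = 0.355 with an estimated correlation), with the survivin gene Birc5 at -1.01 (SE 0.19) and Mki67 at -0.95 (SE 0.15). Of 20 ATF4 targets 1 was higher and 12 lower, also over the list alone (camera adjusted p = 2.7e-07, adjusted p = 0.355 with an estimated correlation), with the pseudokinase gene Trib3 at -1.59 (SE 0.27) and Psat1 at -1.40 (SE 0.14). DNA replication had 11 lower of 20, and 1 higher and 11 lower over the list alone (camera adjusted p = 0.000143), with Fen1 at -0.74 (SE 0.12). Glucose sensing and exocytosis had 8 higher and 2 lower of 23, and 9 and 2 over the list alone (camera adjusted p = 0.0239), with Rab27a at 0.61 (SE 0.10). The last 2 lists had an adjusted p = 0.436 with an estimated correlation. Cholesterol synthesis had 8 lower of 20, also over the list alone (camera adjusted p = 0.000699, adjusted p = 0.644 with an estimated correlation), with the squalene-oxidizing Sqle at -0.87 (SE 0.11). Interferon response had 3 lower of 12, also over the list alone (camera adjusted p = 0.0115, adjusted p = 0.404 with an estimated correlation), with Mx2 at -0.99 (SE 0.19).

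The remaining lists were not called in that comparison over both batches. NRF2 targets split into 6 higher and 7 lower of 21, and 6 and 8 over the list alone (camera adjusted p = 0.436), with Hmox1 at -1.16 (SE 0.24) and Osgin1 at 0.74 (SE 0.11). Metal genes had 1 higher and 4 lower of 6, and 2 and 4 over the list alone (camera adjusted p = 0.0507, and 0.0462 with quantile normalization), with the zinc exporter gene Slc30a1 at -1.44 (SE 0.20). Immediate early genes had 3 higher and 8 lower of 20, also over the list alone (0.344), with Nr4a1 at -1.44 (SE 0.13) and Ier3 at -1.06 (SE 0.14), and their median of -0.023 turned to 0.012 with equal totals. Heat shock genes had 3 higher of 16, and 5 over the list alone (0.159), with the co-chaperone gene Bag3 at 0.45 (SE 0.08). The p53 targets had 3 lower of 13, also over the list alone (0.164), with Fas at -1.38 (SE 0.16) and Ccng1 at -0.52 (SE 0.06). Beta cell transcription factors had 5 higher and 3 lower of 18, also over the list alone (0.931), with Foxa2 at -0.53 (SE 0.08). Insulin granule genes had 1 higher and 1 lower of 19, also over the list alone (0.931), with a median of -0.018 that turned to 0.017 with equal totals and 0.103 with quantile normalization. The miR-29 targets had 2 lower of 18, also over the list alone (0.621), Col5a3 (-1.11, SE 0.25) and Ppm1d (-0.57, SE 0.07), with a median of 0.088, a mean of -0.111 and a downward test. ER chaperones had 1 lower of 19, also over the list alone (0.109), Herpud1 (-0.96, SE 0.13), and glycolysis and hypoxia targets 2 of 15, also over the list alone (0.339), including Pfkp (-0.83, SE 0.13). Both of these lists and the insulin granule genes went opposite ways in the batches. In batch K alone 12 ER chaperones were higher and 2 lower (camera adjusted p = 0.000911), 7 glycolysis genes higher and 2 lower (0.0097) and 8 granule genes higher and 1 lower (0.0097). In batch R alone 13 ER chaperones (4.84e-10), 4 glycolysis genes (5.29e-06) and 2 granule genes (0.00349) were lower, with 0 of each higher by limma. Respiratory chain genes had 2 lower of 17, and 1 over the list alone (0.118), including Cox5a (-0.61, SE 0.14). Ribosomal protein genes had 0 of 18 past limma either way (0.323), but 5 were higher with quantile normalization, 6 over the list alone (0.00325), and 10 in batch K alone (0.000911). Acinar genes had 2 lower of 3, also over the list alone, and fibroblast genes 1 higher of 6, Thy1 (0.46, SE 0.09), also over the list alone (0.562). The 4 duct genes had 0 past limma, and 1 higher and 1 lower over the list alone, and the 2 other endocrine genes 0 either way.

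The RNA changes of the arsenicals against the shared controls correlated across genes with r = 0.617, against a mean of 0.544 (SD 0.0219) in 100 simulations of unchanged groups that share those controls. The covariance was 0.1928 against a simulated 0.0402, a difference of 0.1525. With the controls split between the comparisons r was 0.437 or 0.45, depending on the pairing, and it was 0.489 in batch R alone. Shared rises numbered 1135 and shared falls 1075. Independent lists would share 317 and 358, but these lists share their controls. Genes called in opposite directions numbered 91, and Mt1 was among them.

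ChRO-seq asked which of these changes were seen in nascent transcription, and few genes passed limma in the planned fit. With iAs, 13 of 11803 genes were called, 3 up and 10 down. The Wnt ligand gene Wnt4 fell by 0.88 (SE 0.11, adjusted p = 0.0024), from 559 ± 61.9 to 307 ± 57.7 (SD, n = 4 each) normalized counts, Ssbp2 by 0.97 (SE 0.13) and the glycerol phosphate dehydrogenase gene Gpd1 by 0.98 (SE 0.14), in all 4 iAs libraries. The potassium channel gene Kcnq3 (1.27, SE 0.24), the lysosomal Hexa (1.16, SE 0.20) and the sorbitol dehydrogenase gene Sord (0.91, SE 0.16) rose, and Kif26a (-1.33, SE 0.22), the phosphodiesterase gene Pde2a (-1.07, SE 0.19) and Slc9a3r1 (-0.87, SE 0.15) fell. All 6 of these calls were lost without iAs K3 or without control R2, and some of them also without control R1, iAs R1, iAs R2, control K2, control K3, MAs K4 or MAs R2. At an unadjusted p below 0.05 there were 1356 genes, and edgeR called 14 and DESeq2 140. The count was 267 without iAs K2, 4 without iAs K3, 5 without control R1 and 4 without control R2, and it was 37 in batch K alone, 253 in batch R alone and 0 without the batch term. Equal totals gave 6 rises and 9 falls.

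In ChRO with MAs, 0 genes rose and 11 fell by limma, with 1915 genes at an unadjusted p below 0.05, 9 called by edgeR and 280 by DESeq2. The falls included the beta cell transcription factor gene Neurod1 (-1.08, SE 0.20), the nuclear importin gene Kpna2 (-1.14, SE 0.21), Dcst1 (-1.62, SE 0.24), the serotonin receptor gene Htr5b (-1.18, SE 0.18), Fam111a (-1.04, SE 0.18) and Tex14 (-0.98, SE 0.18). Each of these calls was lost without control R1, MAs R1 or MAs R2, which left 0 genes in each case, and some also without control R2, MAs K4 or iAs R1. The count was 2 without control R2, 53 without control K2, 24 without control K3, 65 without iAs K2, 17 without iAs K3, 39 without MAs K1 and 26 without iAs R2. Batch K alone gave 0 genes and batch R alone 1689.

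MAs against iAs in ChRO gave 610 called genes, 252 higher and 358 lower with MAs. Of 19 mitotic genes 17 were lower, and 19 over the list alone (camera adjusted p = 1.24e-18, adjusted p = 0.279 with an estimated correlation), with Ccna2 at -1.48 (SE 0.23) and Bub1 at -1.18 (SE 0.19). Depdc1 (-1.74, SE 0.27), the neurotrophin gene Bdnf (-1.66, SE 0.30), the adenylyl cyclase gene Adcy8 (-1.86, SE 0.33) and Neurod1 (-1.29, SE 0.20) were lower, and Nckap5l (1.36, SE 0.21), the kinase gene Nek6 (1.32, SE 0.20) and the channel gene Trpc4 (1.31, SE 0.24) were higher, in all 4 MAs libraries. Cholesterol synthesis had 2 lower of 18, Insig1 (-1.02, SE 0.27) and Sqle (-0.96, SE 0.22), and 7 over the list alone (camera adjusted p = 0.00847). The ATF4 list had 1 higher and 2 lower of 19, including Mthfd2 (-1.49, SE 0.31), and 1 and 3 over the list alone (camera adjusted p = 0.0446). Both lists had an adjusted p = 0.679 with an estimated correlation. Insulin granule genes had a median of -0.012 and a mean of 0.009 (upward camera test, adjusted p = 0.567). All 3 of these genes lost their calls without MAs R1 (-0.83 for Insig1, -0.92 for Sqle and -1.29 for Mthfd2), MAs R2 (-0.82, -0.84 and -1.42) or iAs K3 (-1.14, -0.82 and -1.37), and Insig1 also without iAs K2, iAs R1 or iAs R2 (-0.96), the last of which ended the call of Sqle too. DESeq2 called 1102 genes and edgeR 575. The count was 205 without iAs K3, 375 without MAs K4, 405 without iAs R1, 200 without MAs R1 and 128 without MAs R2, and 113 in batch K alone.

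**Figure D3:**
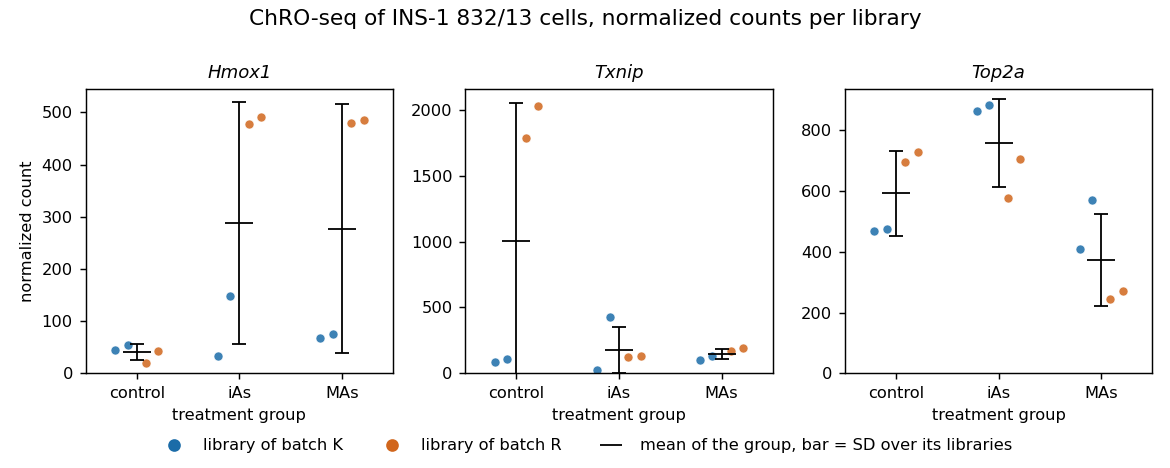
Normalized ChRO counts (linear axes) of Hmox1, Txnip and Top2a in control, iAs and MAs libraries. Each point is 1 library, blue for batch K and orange for batch R, and the bars give the mean and SD; in batch R Hmox1 lies at 20.8 to 43.6 in controls and 478 to 490 in treated libraries, and in batch K at 44.3 to 55.2 in controls and 33.9 to 148 in treated libraries.

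With iAs, 0 list members passed limma over all genes in ChRO. Mitotic genes were shifted up (camera adjusted p = 3.65e-06, 3 of 19 up over the list alone), as were p53 targets (0.0111) and respiratory chain genes (0.0415), and glucose sensing and exocytosis genes were shifted down (6.02e-05, 7 down over the list alone), as were ER chaperones (0.00218), insulin granule genes (0.00556, 4 down over the list alone) and ribosomal protein genes (0.00556). The glucose sensing list kept its call (adjusted p = 0.0193 with an estimated correlation) and the others did not (adjusted p = 0.37 with an estimated correlation). The mitotic shift was in batch K, with a median of 0.838 and 16 of 19 up over the list alone in that batch (camera adjusted p = 1.2e-19), against a median of -0.135 in batch R (0.23). ATF4 targets (camera adjusted p = 1.15e-10 up in batch K, 0.00539 down in batch R) and DNA replication genes (0.0404 up, 0.0031 down) went opposite ways, as did NRF2 targets (0.0247 down in batch K, 4.87e-05 up in batch R). With quantile normalization the calls of insulin granule (0.0581) and respiratory chain genes (0.0873) were lost. The heat shock list had a median of 0 and a mean of -0.075 and was not called. With MAs, mitotic genes were shifted down (camera adjusted p = 4.92e-11, 16 of 19 down over the list alone), as were cholesterol synthesis and glycolysis genes (0.000121 each), beta cell transcription factors (0.0353) and ER chaperones, immediate early, insulin granule and miR-29 target genes (0.0445 each), and NRF2 targets were shifted up (0.0187). Quantile normalization ended the calls of beta cell transcription factors (0.0793), insulin granule (0.151) and immediate early and miR-29 target genes (0.0548 each). None held: the adjusted p was 0.424 for NRF2 targets, 0.535 for ER chaperones, 0.496 for insulin granule genes and 0.393 for the others, each with an estimated correlation. In batch R alone 18 mitotic genes fell with MAs, and in batch K alone 0 passed limma.

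The ChRO libraries of the batches differed in their response. Hmox1 had a log2 change of 3.96 in batch R and 0.52 in batch K with iAs (adjusted p of the difference = 0.0322), and 3.96 and 0.53 with MAs. Top2a stood at -1.47 and 0.03 with MAs, and Txnip at -3.91 and 0.07 with iAs (adjusted p of the difference = 0.109, not past the test); these genes were chosen after their values were seen. The difference between batches passed the test for 21 genes with iAs, Hmox1 among them, and for 324 genes with MAs, Hmox1 and Top2a among them. The ChRO changes of the batches correlated across genes with r = 0.082 for iAs and 0.075 for MAs. On a mean score over 1862 genes changed in RNA in a single direction by both arsenicals, centred within batch, the ChRO library labelled iAs K2 stood at -0.296, below the libraries labelled control K2 (0.017) and control K3 (0.018), whereas batch R controls stood at -0.326 and -0.319 and its treated libraries at 0.052 to 0.261.

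RNA and ChRO changes were compared over 11171 genes measured in both. The changes correlated with r = 0.436 (rho = 0.372) for iAs and r = 0.491 (rho = 0.471) for MAs. Within batches, a comparison added after the data were seen, r was 0.484 and 0.626 in batch R and in batch K 0.123 and 0.007, so the relation did not hold in batch K with MAs. Of the 13 genes called in ChRO with iAs, 12 were called in RNA in the same direction, and with MAs 7 were called in both in the same direction. The ChRO changes of the arsenicals correlated with r = 0.257, against 0.5 in simulations of unchanged groups, with a covariance of 0.0386 against a simulated 0.0449.

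The RNA change minus the ChRO change differed from 0 for 58 genes with iAs, 39 with the RNA change above the ChRO change and 19 below it, and for 186 genes with MAs, 127 above and 59 below. With iAs the RNA change of the nitric oxide synthase gene Nos1 lay below its ChRO change (-2.06, SE 0.31, adjusted p = 0.00288) and that of Lrrc24 above it (1.35, SE 0.22). With MAs the RNA changes of Kcnj5 (3.27, SE 0.54), the peptide hormone precursor gene Pomc (2.04, SE 0.35) and Fam149a (2.18, SE 0.29) lay above, and the contactin gene Cntn3 (-1.28, SE 0.26) below. Of the 10 genes named by rule, 8 lost their call when some 1 library was left out with iAs, all but Nos1 and Lrrc24, and 5 with MAs, where Kcnj5, Pomc, Fam149a and Cntn3 kept theirs. Separate fits of the assays, which add their errors, gave 2 and 10 genes. There Nos1, Kcnj5, Fam149a and Pomc kept their calls, and the other 16 of the 20 named lost theirs, Lrrc24 and Cntn3 among them. Batch K alone gave 1419 and 868 genes and batch R alone 0 (613 at an unadjusted p below 0.05) and 11, and ChRO in batch K is where Hmox1 and Top2a changed less than in batch R. With equal totals the iAs split was 32 higher of 58.

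Leaving out 1 library moved the 58 genes of Nos1 and the others to 19 (RNA control K2), 21 (RNA control K3), 26 (RNA iAs K2), 10 (RNA iAs K3), 12 (RNA control R1), 36 (RNA control R2), 465 (RNA iAs R1), 15 (ChRO control K2), 17 (ChRO control K3), 36 (ChRO iAs K2), 149 (ChRO iAs K3), 157 (ChRO control R1), 171 (ChRO control R2) or 215 (ChRO iAs R1). It moved the 186 genes of Kcnj5 and the others to 85 (RNA control K2), 83 (RNA control K3), 112 (RNA MAs K1), 114 (RNA MAs K3), 123 (RNA MAs K4), 87 (RNA control R1), 110 (RNA control R2 or RNA MAs R1), 84 (RNA MAs R2), 117 (ChRO control K2), 75 (ChRO control K3), 309 (ChRO control R1) or 119 (ChRO MAs R1). Mitotic genes had lower changes in RNA than in ChRO with iAs (camera adjusted p = 7.98e-08) and MAs (0.00028). So did ribosomal protein genes (0.0308 and 0.00131). Insulin granule genes (1.41e-05 and 8.55e-05) and NRF2 targets (1.41e-05 and 0.0162) had higher ones. Glycolysis genes were lower with iAs (0.0338) and ATF4 (0.0412) and DNA replication genes (0.00755) with MAs, and immediate early (0.0475) and interferon genes (0.0338) higher with iAs. None held with an estimated correlation (adjusted p 0.372 to 0.746 with iAs, 0.566 to 0.705 with MAs). All used batch K ChRO (r with RNA 0.123 for iAs, 0.007 for MAs). ATF4 targets with iAs (-0.075) and p53 targets with MAs (-0.022) had negative medians with upward, uncalled tests.

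Small RNA-seq asked which microRNAs differed with iAs. miR-146a-5p, a microRNA induced by inflammatory signaling, rose 2.23-fold, from 151 ± 55.3 to 327 ± 82.6 (SD, n = 5 each) normalized counts (log2 1.15, SE 0.12, adjusted p = 0.000346). miR-29a-3p, an abundant microRNA of the family that targets collagens and DNA methyltransferases, rose 1.49-fold, from 30260 ± 5691 to 47260 ± 18940 (SD, n = 5 each; log2 0.57, SE 0.10, adjusted p = 0.0077). miR-134-5p fell 2.55-fold, from 175 ± 96.9 to 66.6 ± 33.5 (log2 -1.35, SE 0.12), and miR-410-3p (-0.92, SE 0.15), miR-541-5p (-0.76, SE 0.08) and the miR-409a-3p features with an offset in their names (-1.14, SE 0.14 and -1.10, SE 0.13) fell too. miR-126a-3p (0.56, SE 0.10) and miR-22-3p (0.34, SE 0.05) rose, in all 5 iAs libraries, and miR-375-3p, a microRNA enriched in beta cells, stood at 0.06 (SE 0.07, adjusted p = 0.706). In all, 55 of 1117 features passed, 27 up and 28 down, and 13 of them were offset features, whose meaning is not given in the sources used here.

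Of the 3 measured members of the miR-29 family 2 rose and 3 rose adjusted over the list alone. miR-29b-3p stood at 0.48 (SE 0.11, adjusted p = 0.0274), a call that was lost with equal totals (0.46, adjusted p = 0.0849) and without control R2 (0.49), control R3 (0.47), iAs R2 (0.48), control K2 (0.50) or iAs K2 (0.39). miR-29c-3p stood at 0.36 (SE 0.12, adjusted p = 0.109) and passed without iAs R1 (0.44, adjusted p = 0.0425). Of 12 stress and p53 responsive microRNAs 3 rose, including miR-146a-5p and miR-22-3p, and 5 rose and 1 fell over the list alone. Of 4 microRNAs of other cell types 1 rose, miR-126a-3p, which endothelial cells express, also over the list alone. Of 8 beta cell enriched microRNAs 0 passed limma over all features and 2 rose over the list alone, miR-153-3p (0.32, SE 0.08) and miR-184 (0.32, SE 0.11), and of 4 members of the miR-200 family 0 passed and 1 rose over the list alone, miR-200c-3p (0.18, SE 0.06). The 8 let-7 members, the 3 of the miR-183 cluster and the 3 of the miR-17-92 cluster had 0 past limma either way. Over all features 204 had an unadjusted p below 0.05, and edgeR called 53 and DESeq2 111.

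**Figure D4:**
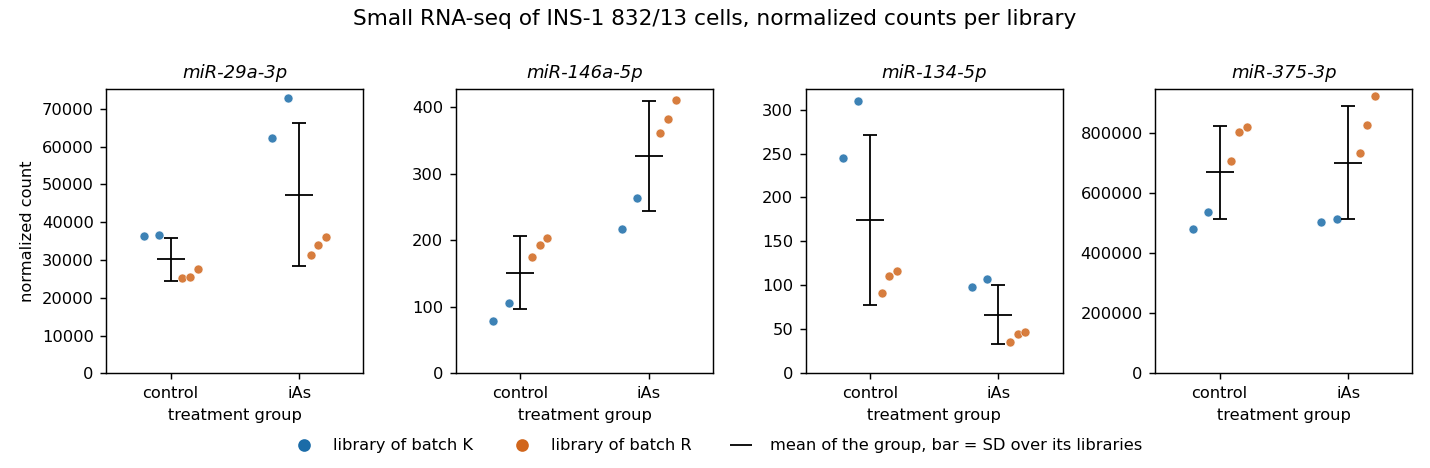
Normalized small RNA counts (linear axes) of miR-29a-3p, miR-146a-5p, miR-134-5p and miR-375-3p in control and iAs libraries. Each point is 1 library, blue for batch K and orange for batch R, and the bars give the mean and SD; within each batch miR-146a-5p is higher and miR-134-5p lower with iAs.

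Within batches, miR-29a-3p stood at a log2 change of 0.89 in batch K and 0.37 in batch R, miR-146a-5p at 1.37 and 1.01 and miR-134-5p at -1.41 and -1.31, and only 1 feature differed between batches past the test. Batch K alone gave 0 features by limma (15 by edgeR) and batch R 13. Their changes correlated across features with r = 0.137. Equal totals gave 36 features, 10 up and 26 down, no trend 25, and a fit without the batch term 0. The count was 29 without control R2, 31 without iAs R2, 25 without control K2, 32 without iAs K1 and 24 without iAs K2, and miR-146a-5p, miR-29a-3p and miR-134-5p kept their calls in each of these fits.

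With MAs, 0 of 1098 small RNA features passed limma in 4 MAs against 2 control libraries, with 124 at an unadjusted p below 0.05, a smallest adjusted p = 0.0522, 0 called by edgeR and 28 by DESeq2. miR-29a-3p stood at 52600 ± 5806 (SD, n = 4) against 36470 ± 918 (SD, n = 2) normalized counts, a log2 change of 0.52 (SE 0.12, adjusted p = 0.184) that was higher in 4 of 4 libraries, and miR-134-5p at -0.82 (SE 0.14, adjusted p = 0.115). miR-543-3p (-1.44, SE 0.23), miR-449c-5p (-1.14, SE 0.20) and an offset form of miR-22-3p (1.14, SE 0.15) had small p-values but did not pass. Each of the 8 microRNA lists had 0 members past limma over all features, and over the lists alone miR-29a-3p alone rose. The count was 3 without control K1 and 2 without control K2. In the edgeR fit to recovered batch K reads, added after the data were seen, 3 features were higher with MAs than with iAs. They were 2 offset forms of miR-409a-3p (0.80 and 1.08) and miR-6332, and 101 had an unadjusted p below 0.05.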

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

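The response score of single libraries, the correlation of RNA with ChRO changes within each batch and batch-balanced splits were chosen after results were seen. Genes whose change differed between the batches were found by testing that difference for every gene. With MAs 2006 genes differed in RNA, 686 more positive and 1320 more negative in batch R, and 324 in ChRO, 87 and 237. The folate enzyme gene Mthfd2 stood at a log2 change of -0.93 in batch K and -2.40 in batch R with MAs in RNA, and the ER stress gene Herpud1 at -0.65 and -1.49. With iAs 6 genes differed in RNA, Mthfd2 among them at 0.21 and -0.67, and 21 in ChRO, Hmox1 among them. In small RNA with iAs 1 feature differed, miR-6332, at -4.55 in batch K and 0.41 in batch R.

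A single library stood apart from the others of its group for 20 of 490 groups of libraries of the named genes, by the size of its gap to the nearest other library as a share of the range of the group. Chance gives about 1 in 20 groups, or 24.5 here. In RNA with iAs, library R2 stood apart for Ltb (185.6 normalized counts against 108.6 to 115.9, gap share 0.906), Neurod1 (6751 against 7866 to 8024, 0.876), Sox9 (73.84 against 42.63 to 44.69, 0.934), Top2a (15790 against 20450 to 21160, 0.867) and the clock gene Bhlhe40 (6211 against 4236 to 4541, 0.846). Library R1 stood apart for Cacna1a (8126 against 5047 to 5452, 0.868) and Scg2 (38590 against 44760 to 45630, 0.876). Among RNA controls, K3 was highest for Gsta1 (26.15 against 3.811 to 6.857, 0.864), Ltb (50.56 against 13.56 to 19.3, 0.845) and Vgf (42610 against 33180 to 34730, 0.835), and K2 was highest for Cacna1a (15290 against 12300 to 12700, 0.868). In RNA with MAs, R1 was highest for Trib3 (2087 against 758.8 to 1139, 0.714) and Per3 (852.1 against 465 to 600.4, 0.65), and R2 was lowest for Eprs (19020 against 20740 to 21260, 0.765) and for Inhbe, listed at 0 against 3.711 to 5.782 (0.642). In ChRO, the library labelled iAs K2 was lowest for Kcnq3 (110.3 against 246 to 272.8, 0.835) and iAs R1 highest for Pomc (184.5 against 58.17 to 77.16, 0.85), while MAs R2 was highest for Nek6 (167.1 against 125 to 131.6, 0.845) and MAs R1 for Trpc4 (722.1 against 554.6 to 559.7, 0.969). In small RNA, MAs K3 was highest for miR-543-3p (26.1 against 20.54 to 21.45, 0.836).

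The first pattern weighed was that ChRO changes of batch K did not follow the RNA changes of batch K, with r across genes of 0.123 for iAs and 0.007 for MAs against 0.484 and 0.626 in batch R. The values argue against sequencing depth, since batch R libraries thinned to 998734 reads each still gave r = 0.59 for MAs (SD 0.0035 over 20 draws), and against the scaling by the authors, since TMM factors on the recovered reads gave r = 0.006 in batch K. Mislabelled ChRO libraries of batch K remain a candidate explanation: on the 1862 genes changed in RNA by both arsenicals, the library labelled iAs K2 scored -0.296, below the libraries labelled control at 0.017 and 0.018, and the library labelled iAs K3 scored 0.184. The libraries labelled MAs K1 and MAs K4 scored 0.042 and 0.036, close to those controls, so a wrong label on 1 library would not account for the whole pattern. A different exposure or harvest of the batch K ChRO cultures was not tested and stays open.

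The next pattern was the 2006 genes whose RNA change with MAs differed between batches. Scaling is argued against, since quantile normalization gave 2336 genes. A part of the count may rest on single libraries: it was 652 without MAs R1, 1035 without control K2, 1071 without control R1 or control R2, and 3970 without iAs R1 or iAs R2. With 2 MAs libraries in batch R, an odd library and a difference between batches cannot be told apart for the genes lost without MAs R1. No biological explanation was tested, because the labels used here give the batches no meaning.

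The last pattern was the higher miR-29a-3p with iAs. Scaling is argued against, since the lowest log2 change over equal totals, quantile and TMM scaling was 0.556, and so is a single library, since the lowest change with 1 library left out was 0.492. A rise of miR-29a-3p with iAs is therefore the hypothesis that these tests leave, found and tested on the same libraries.

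Other splits of the libraries into groups of the same sizes were set beside each count, in fits of the compared groups alone. The real split led in RNA with iAs (3527 genes, others at most 4, 1 of 34 as large). It led with MAs (6319, at most 3, 1 of 99) and MAs against iAs (2698, at most 3, 1 of 99). It led in ChRO with MAs against iAs (617, at most 0 by limma, 1 of 34). For RNA minus ChRO with MAs it gave 609 (at most 3, 1 of 100). For ChRO with MAs 1 of 34 splits, the real one, gave 44 genes and the others at most 1, but limma gave 0 in batch K alone (619 at an unadjusted p below 0.05) and without control R1, MAs R1 or MAs R2 (1348, 1219 and 1182). Moving libraries between batches, these splits do not exclude chance. Only 18 splits of 4 against 4 libraries keep the batches balanced, too few for a share under 0.05, with a highest other of 1 for RNA with iAs, 1 for ChRO with MAs and 0 by limma for ChRO with MAs against iAs. The 90 balanced splits exclude chance for RNA with MAs (highest other 81) and MAs against iAs (629). Chance can also be excluded for small RNA with iAs (55 features, 1 of 100, and 1 of 60 balanced splits, highest other 11). Yet a split of control R1 and all batch K libraries against the rest gave 46 and follows the batches. Batch K alone gave 0 by limma (148 unadjusted, 15 in an edgeR fit added later) and batch R alone 13. Chance cannot be excluded for ChRO with iAs, where 3 of 34 splits gave at least the 12 genes of the real split and the highest other gave 32, with control K2 in the place of the library labelled iAs K2. For RNA minus ChRO with iAs 8 of 100 splits gave at least the 19 genes of the real split, and the highest other gave 2195. Of the 7 others as large, 6 kept the real RNA groups whole and 1 the real ChRO groups, so they hold a treatment effect, and the 90 splits that broke up both gave at most 1. These splits do not settle whether chance can be excluded.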

How the results depend on the processing

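Some tests in this part were chosen after results were seen. They were the fits of RNA minus ChRO in each batch, edgeR in batch K, the count over distinct mature microRNAs and the replicate block. The RNA counts kept within 1.5-fold under other pseudocounts, filters, scalings and fits of the compared groups, and so did the small RNA count with iAs under edgeR (53) and over distinct microRNAs (50). The planned test of microRNA seed sites needs 3' UTR sequences and was not run. Where a library was left out and a single one remained in a group and batch, it was assumed to vary like the other groups. In what follows, triples give iAs, MAs and MAs against iAs, and the cause was not tested unless stated.

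Without a batch term the counts were 2045, 2744 and 1586 in RNA (4125, 4738 and 3255 with it), 0, 0 and 38 in ChRO (13, 11 and 610), 0 for small RNA with iAs (55), and 1 and 4 for RNA minus ChRO with iAs and MAs (58 and 186). The limma counts of 0 stood beside 786, 1166 and 58 at an unadjusted p below 0.05, and edgeR with the batch term gave 14, 9 and 53. Batch K alone gave 5033 for MAs against iAs in RNA and 37, 0 (619 unadjusted) and 113 in ChRO. There small RNA with iAs gave 0 by limma (148 unadjusted, 15 by edgeR) and RNA minus ChRO 1419 and 868. Batch R alone gave 186, 2868 and 1285 in RNA, 253 and 1689 in ChRO against control, 13 for small RNA, and 0 (613 unadjusted) and 11 for RNA minus ChRO; fits of 1 batch have fewer libraries.

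The planned block on title numbers was not run, as columns could not be matched to titles. A replicate block on the number in the column name within its batch gave 3202, 3544 and 2010 genes in RNA, 17, 598 and 528 in ChRO, 9 and 5 small RNA features with iAs and MAs, and 5 and 19 genes for RNA minus ChRO, with fewer degrees of freedom. The numbers did not pair the libraries throughout: over 27 pairs of the same number, the correlation of deviations from the means of their group and batch ran from -0.213 to 0.172 and was over 0.1 in 6. Each library correlated best with its own number in RNA with iAs (4 of 4), against 0 of 4 in ChRO and 2 of 5 in small RNA with iAs, and 2 of 4 in RNA with MAs against either group.

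DESeq2 called 140, 280 and 1102 genes in ChRO, 111 small RNA features with iAs and 28 with MAs, where limma gave 0 (124 unadjusted) and edgeR 0. Without a filter ChRO gave 8, 5 and 347 genes, with more genes tested, and small RNA with MAs 12 features. A mean of at least 100 gave 20 ChRO genes with iAs and 110 genes for RNA minus ChRO with MAs. A pseudocount of 8 gave 24 ChRO genes with MAs, 151 for RNA minus ChRO with iAs and 2 small RNA features with MAs. For ChRO with MAs, equal totals gave 5 genes, quantile normalization 4 and only the compared groups 44. Small RNA with iAs gave 36 features with equal totals and 25 without trend. Separate fits of RNA and ChRO, which add their errors, gave 2 and 10 genes for their difference. Of 44 gene list calls 3 were left with an estimated correlation and 38 with quantile normalization, which gained 3 others. No scaling moved the median of all genes by over 0.1, with 0.064 the largest shift.

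With 1 library left out, RNA counts ran from 2620 (without iAs K3) to 5370 (iAs R1) for iAs, 3635 (control R1) to 5890 (iAs R2) for MAs and 2247 (iAs K3) to 4143 (iAs R1) for MAs against iAs. ChRO counts ran from 4 (iAs K3 or control R2) to 267 (iAs K2) for iAs, 0 (control R1, MAs R1 or MAs R2, with 1348, 1219 and 1182 unadjusted) to 65 (iAs K2) for MAs and 128 (MAs R2) to 778 (iAs K2) for MAs against iAs. Small RNA counts ran from 24 (iAs K2) to 62 (control R1) with iAs and from 0 (each MAs library, with at least 79 unadjusted) to 3 (control K1) with MAs. RNA minus ChRO ran from 10 (RNA iAs K3) to 465 (RNA iAs R1) with iAs and from 75 (ChRO control K3) to 309 (ChRO control R1) with MAs.

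The correlation of the iAs and MAs changes was 0.489 in batch R alone and 0.437 and 0.45 with split controls in RNA (0.617), and 0.061 in batch K alone, 0.579 in batch R alone, and -0.001 and 0.12 with split controls in ChRO (0.257), where the split controls share no libraries. For MAs against iAs in RNA, the log2 change of Gcg turned to 0.36 in batch K alone, that of Nr4a3 to 0.12 and that of Slc2a2 to -0.15 in batch R alone. Over 12566 refits of single named genes under the alternatives, 11344 kept direction and call, 1121 kept direction but lost the call, 98 kept direction and gained one, and 3 turned. What depth limits was tested for ChRO only: batch R libraries thinned to the 998734 reads of the smallest library gave a correlation of RNA with ChRO changes of 0.59 with MAs, against 0.626 unthinned.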

Other observations

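The clock, synthetase and proteasome gene groups, the microRNA region and the comparisons with random lists were chosen after results were seen, whereas the miR-29 target list and its camera test were fixed before. Circadian clock genes fell with both arsenicals in RNA. Of 17 measured clock genes 9 fell and 1 rose with iAs (camera adjusted p = 1.33e-05 over 3 added groups, adjusted p = 0.0547 with an estimated correlation), and 11 fell and 1 rose with MAs (5.24e-05, adjusted p = 0.0644 with an estimated correlation). With iAs the clock output factor gene Hlf fell by 2.18 on the log2 scale (SE 0.28), Per3, a member of the period family of clock repressors, by 1.41 (SE 0.18) and Bhlhe40 by 1.29 (SE 0.25). With MAs Ciart, another clock repressor gene, fell by 1.89 (SE 0.18), Hlf by 1.79 (SE 0.25) and the cryptochrome gene Cry1 by 1.47 (SE 0.11), whereas the other cryptochrome gene, Cry2, rose by 0.32 (SE 0.06) with iAs and 0.26 (SE 0.05) with MAs. These calls held with equal totals, with quantile normalization and with each library left out. In ChRO 0 clock genes passed limma against control, while the group was shifted down with iAs (camera adjusted p = 2.68e-05, adjusted p = 0.102 with an estimated correlation) and with MAs (0.00317, adjusted p = 0.477 with an estimated correlation).

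Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 3 rose with iAs (camera adjusted p = 0.0869), while 9 fell and 1 rose with MAs (0.047, adjusted p = 0.583 with an estimated correlation). Set directly against iAs, MAs had 11 lower and 1 higher (9.81e-05, adjusted p = 0.376 with an estimated correlation), with Cars at -0.91 (SE 0.12), Eprs at -0.52 (SE 0.08) and Gars at -0.52 (SE 0.12). Of 33 proteasome subunit genes 9 rose with iAs (1.33e-05, adjusted p = 0.489 with an estimated correlation), including Psmd5 (0.58, SE 0.07) and Psmd9 (0.38, SE 0.10), and 3 rose with MAs (0.358). Against iAs 7 proteasome genes were lower with MAs (9.81e-05, adjusted p = 0.544 with an estimated correlation). Proteasome rises with iAs numbered 16 with equal totals, 3 without control K2 and 5 without control K3, iAs K3, control R1 or iAs R2, and those with MAs 8 with equal totals or quantile normalization. The 7 lower with MAs than with iAs became 11 with equal totals, 4 without MAs K2, 2 without iAs K3 or MAs R1 and 1 without MAs R2. Synthetase rises with iAs numbered 1 without iAs K3 (4, with 1 fall, without iAs R2), and those with MAs 2 without iAs R1 or with quantile normalization. The calls of these 5 genes in the comparisons given held with other scalings and with each library left out. None of the genes of the 3 groups is in a list fixed earlier.

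The microRNAs that fell with iAs included several encoded between Meg3 and Dio3 on chromosome 6, an imprinted region with 59 microRNA genes in the GRCr8 gene table. Of 23 measured distinct microRNAs of the region 21 were lower with iAs and 8 of these passed limma, with none higher past the test. miR-382-3p stood at -0.67 (SE 0.13, adjusted p = 0.0137) and, with miR-134-5p, miR-410-3p and miR-541-5p, kept its call in every fit with 1 library left out. Of the 8 calls, 4 were kept without control R2, iAs R3, control K2 or iAs K2, 5 without control R3, iAs R2 or iAs K1, and 6 or 7 without any other library or with other scalings. Without the features by which the region was noticed, 15 of the 17 others were lower, 3 past limma. Their median was -0.397, at percentile 0.2 (0.1 in batch R, 9.3 in batch K) of 10000 random lists matched on mean level (median 0.006). Members of 1 region may vary together, unlike random lists, so the hypothesis of a joint fall beyond those features stays open. With MAs, in batch K alone, 19 of 22 such features were lower (median -0.289, percentile 1), and 0 of the 28 measured passed limma.

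A further hypothesis was that miR-29 lowers its targets after transcription, in which case the RNA change of literature targets would lie below their ChRO change. Over 16 targets measured in both assays, the median of the RNA change minus the ChRO change was -0.268 with iAs, at percentile 2.9 of 10000 random lists matched on mean expression, whose median was -0.026. It was at percentile 1.1 in batch K and 4.4 in batch R. With MAs the median was -0.093, at percentile 25.1, with 4.4 in batch K and 55.1 in batch R. The iAs values are consistent with the hypothesis, but camera did not call the list (adjusted p = 0.0875, adjusted p = 0.372 with an estimated correlation), and the ChRO libraries of batch K are those whose labels are in doubt.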
